A study of Mus musculus with 6 samples.

How the data were processed

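Chromatin was taken from flash-frozen tumours of SmoM2 mice, and ChIP with an antibody against YAP1 and sequencing on an Illumina NextSeq 500 were done by a service company, per the labels' protocols. Of the 6 libraries in the series, 4 are YAP1 ChIP libraries with 1 peak list each, and the 2 pooled inputs were not analysed here. The tissue is labelled MB and was taken to be medulloblastoma, the tumour this genotype is known for. BWA, HOMER 4.11 and the mm9 build are named in the submitters' processing notes, with no role or order. The peak caller, its version, its threshold and the control it used are not given in the sources used here. In particular, no source says whether a pooled input served as control. If it did, libraries of the same replicate number may share 1 control, and part of their overlap may come from it.

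Each list was called on 1 library and is in narrowPeak form. For each peak the authors deposited a fold enrichment at the peak (a ratio over a background that is not described), the −log10 of a p-value and of a q-value, a score, and the summit. The authors' deposited score was the whole part of 10 times the −log10 q-value for 99.976% of the peaks of female 2 and 100% of those of the other lists, compared exactly after rounding down. The lowest deposited −log10 q was between 1.30 and 1.35 in the 4 lists, so each list stops near q = 0.05. Fold enrichments ran from 1.31 to 33.0 over all lists. Peak numbers and p-values rise with sequencing depth, and the lists carry no read counts. For this reason, heights were used to rank or filter peaks within a list and were not tested between lists.

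Contig names and peak ends past the chromosome ends of later builds matched mm9. The gene table at hand is of GRCm38, and coordinates were not carried between builds. Promoter shares, TEAD and other motif shares, and the 24 gene lists had been planned with an annotation and sequence of mm9, within 10 kb of a transcription start for the gene lists. These were not used here, so regions are named by position and no gene is named for them.

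Groups were taken from the titles, which the descriptions share. A Sex tag goes against both in 2 of the 4 libraries, and it also gives a sex to each pooled input. Replicate numbers 1 and 2 go with a shared code in the descriptions, so a number marks libraries that were handled under 1 code. The code is the source of the pairing. A correlation of deviations could not be had from lists without counts. Peak numbers were compared with a two-sided exact permutation test of the difference in mean log2 number, which has 6 splits, and paired by number with an exact sign-flip test.

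Peaks of the 4 lists that overlapped by at least 1 bp were chained into merged regions, and a library held a region if it had a peak in it. Overlap of 2 lists was the share of peaks of the shorter list that overlapped the other list. Chance was estimated from 100 circular shifts within chromosomes, which wrap at the last peak end of any list. Shares have 95% exact Clopper-Pearson intervals, and a count of 0 was given the limit that 3 counts would set. Both cover counting error only. Peak density per chromosome used the position of the last peak end as length. X and autosomal peaks were compared with Fisher's exact test, and odds ratios of the 2 numbers were pooled with the Mantel-Haenszel method. The rule for regions named by position was to take, for regions in all 4 libraries, in both female and neither male, and in both male and neither female, the 10 with the best worst rank by fold enrichment over the lists concerned. The groups, the comparisons of peak numbers, merged regions, pairwise overlaps and sex chromosome shares, and the naming rule were chosen before the data were examined. The Fisher and Mantel-Haenszel comparisons of X, the ratios per chromosome, the bins by strength and the counts of regions by rank were added after seeing the data.

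The other settings tried were a −log10 q of at least 5, lists cut to the length of the shortest (4155 peaks, by p-value), chromosomes 1 to 19 and X, an overlap of at least 50% of both peaks, summits within 200 bp, each library left out, groups from the Sex tag, and pairing by number. Lists of the top 500, 1000 and 2000 peaks, equal length by fold enrichment, and equal length by p-value for the pairwise overlaps were added after seeing the data. The merging step was tested on simulated data of 18571 regions, in which sets of 500 or more regions were recovered at 99.4% to 100.1% of their size. Simulated peaks were placed at random along chromosomes, and shared ones nearly coincided. This checks the merging itself, and not clustered peaks or sets as small as the male pair alone. Independent simulated lists of the lengths of female 1 and male 1 overlapped by 0.481% of the shorter list's peaks, against a mean of 0.414% after shifts. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.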

Results

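YAP1 ChIP-seq peak lists were compared between medulloblastomas of female and male mice. The animals carried SmoM2, a constitutively active form of the Hedgehog receptor component Smoothened, switched on by a Cre recombinase under the human GFAP promoter. YAP1 is the transcriptional co-activator at the end of the Hippo pathway, and it is known to reach DNA through partner factors such as the TEAD proteins. From the series title, the question was whether the function of YAP1 differs between the sexes. There were 2 female and 2 male libraries, each with a replicate number (1 or 2) from its title, and each with its own list of peaks. The female lists held 16145 (female 1) and 16769 (female 2) peaks. The male lists held 4155 (male 1) and 9470 (male 2) peaks. The peaks covered 5636 kb and 6103 kb in the female lists, and 1135 kb and 3076 kb in the male lists. Median peak width was 292 and 311 bp in female 1 and 2, and 235 and 278 bp in male 1 and 2. The read depth behind each list is unknown, because the files give no counts, and peak numbers depend on depth. The labels do not say whether the libraries came from separate animals, so the spread given here may be technical. All positions are 1-based and on mm9, the build named in the submitters' processing notes.

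The libraries shared a set of peak regions. Merging the 4 lists gave 25223 regions, of which 1990 (7.89%) were present in all 4 libraries. The count depended on the settings: it was 735 at −log10 q of at least 5, 774 at equal list length by p-value and 1288 with an overlap of at least 50% of both peaks, and 5748 regions were in the 3 other libraries without male 1. No region was common to all 4 lists in any of 100 circular shifts of the lists along the chromosomes. The shifts show that positions coincide, and they cannot tell YAP1 binding from other sources of peaks at the same places. The shared regions included the strongest peaks: 16 of them ranked within the first 100 peaks by fold enrichment in every list. The region on chromosome 14 from 64224528 to 64225294 ranked 4th or better in all 4 lists, with fold enrichments of 26.7 in female 1, 25.3 in female 2, 13.6 in male 1 and 19.8 in male 2. A pair of neighbouring regions followed on chromosome 19. The region from 40968406 to 40970422 was the highest peak of female 1 (33.0-fold) and of male 1 (21.4-fold), and reached 21.9-fold in female 2 and 16.4-fold in male 2. The region from 40947319 to 40948622 ranked 3rd in both female lists, 9th in male 1 and 2nd in male 2, with fold enrichments from 10.5 in male 1 to 25.5 in female 2.

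**Figure D1:**
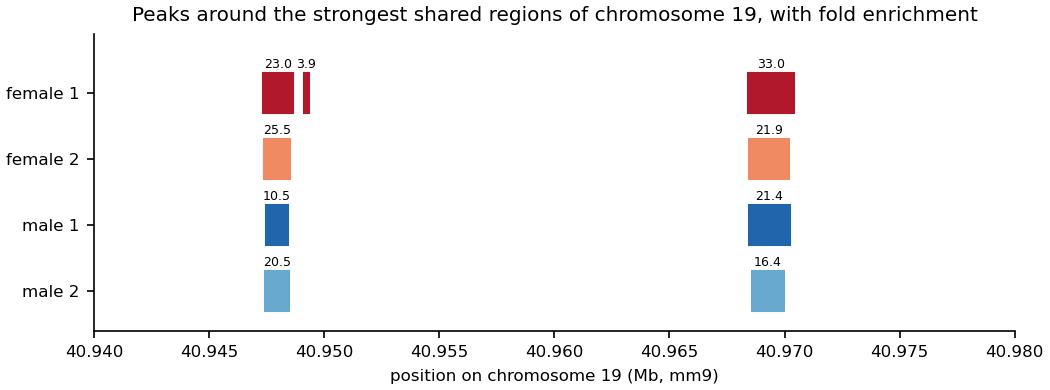
Peaks of each library around the 2 strong regions of chromosome 19 (x axis, position in Mb, mm9), drawn to scale as boxes, one row per library, with the authors' fold enrichment above each. Both strong regions appear in all 4 lists, and female 1 has a further weak peak at 3.93-fold.

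The other 7 regions of the 10 best-ranked shared ones lay on chromosomes 11 (95895571 to 95896507), 1 (82720824 to 82721839), 4 (150481490 to 150482865), 7 (69563916 to 69565522), 13 (18035962 to 18037135), 10 (79131617 to 79132578) and 1 (173340676 to 173341697). The chromosome 11 region had fold enrichments of 18.4 and 16.5 in female 1 and 2, and of 12.3 and 11.1 in male 1 and 2. The first chromosome 1 region had 20.8 and 16.4 in the female lists, and 12.1 and 10.3 in the male lists. Fold enrichments are the authors' values for single peaks. They rank peaks within a list, and they were not tested between lists. Among chromosomes 1 to 19 and X, chromosome 11 was the most densely occupied in every list, with 11.1 peaks per Mb in each female list, 3.01 in male 1 and 6.65 in male 2. Of the same 20 chromosomes, X was the least densely occupied, with 1.60 and 1.80 peaks per Mb in female 1 and 2, and 0.222 and 0.529 in male 1 and 2.

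More peaks were called in the female than in the male libraries. The mean was 16457 ± 441 (SD, n = 2) in females and 6812 ± 3758 (SD, n = 2) in males. The female to male ratio of geometric means was 2.62. It was 3.89 in replicate number 1 and 1.77 in replicate number 2. Both female lists were longer than both male lists, which gives p = 0.33 in the two-sided exact permutation test. That is the smallest p that 2 libraries against 2 can reach, so the design cannot show a difference at 0.05. The 2 male lists differed from each other by 2.28 times, the 2 female lists by 1.04 times. Without male 1, the ratio was 1.74, and without male 2 it was 3.96.

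Most regions in a male list were also in a female list, and the reverse was less so. Of the 11057 regions in a male list, 9118 (82.5%) were also in a female list. Of the 23284 regions in a female list, the same 9118 made up 39.2%. Both female and neither male library held 2790 regions, and both male and neither female library held 23. Leaving out 1 library loosens the rule behind these counts, so they rose by construction. Females alone had 3313 regions without male 1, 6554 without male 2, 8627 without female 1 and 8643 without female 2, where the remaining female library stands for its sex. Males alone had 1199 without male 1, 768 without male 2, 124 without female 1 and 100 without female 2. The lists differ in length, which bears on these counts. With each list reduced to its 4155 strongest peaks by p-value, the counts were 344 female and 202 male regions, and by fold enrichment 241 and 245. Such a cut only removes peaks. The male regions beyond the 23 therefore lay in regions that held a female peak in the full lists, and they do not count binding confined to males. At equal list length by p-value, pairing the libraries by replicate number gave larger counts and crossing them gave a smaller total. The libraries of replicate number 1 held 512 regions that neither library of number 2 had, and the reverse count was 752. The sex pairs held 546 such regions in total and the number pairs 1264. The crossed pairs held 439, with 303 (female 1 with male 2) and 136 (female 2 with male 1). Each of these counts can include regions whose peak in another list was cut. With lists as deposited, sex pairs and number pairs were in the other order: totals were 2813 for sex, 2125 for number and 543 for crossed pairs.

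**Figure D2:**
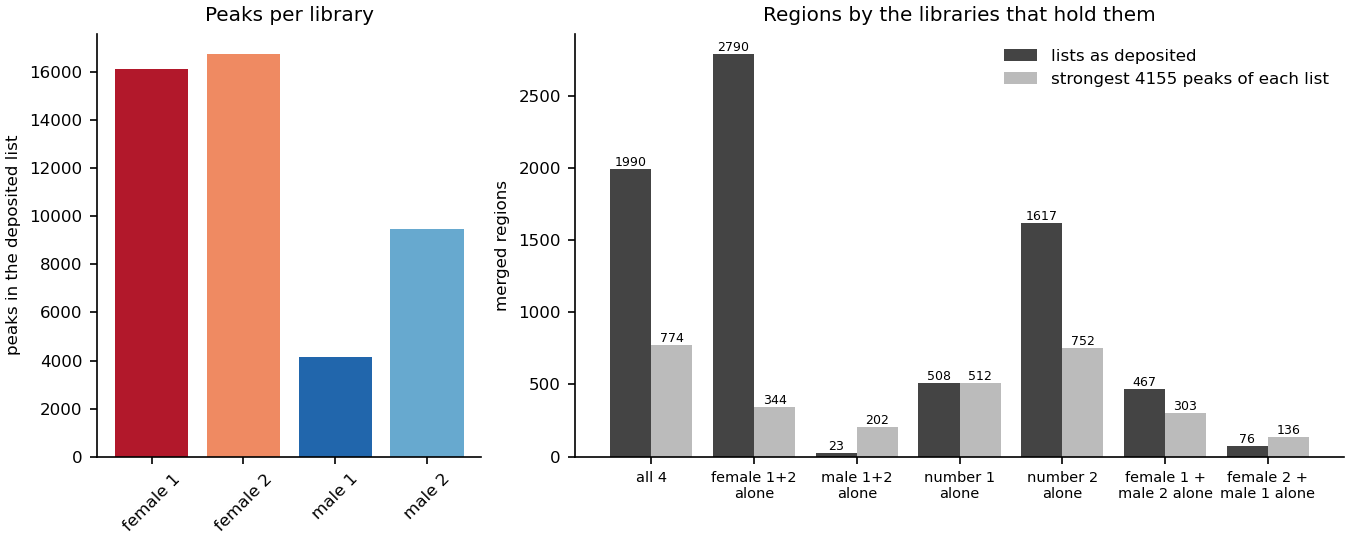
Left, number of peaks in each deposited list, female libraries in reds and male libraries in blues. Right, number of merged regions by the libraries that hold them and no others, for lists as deposited (dark) and for the strongest 4155 peaks of each list by p-value (light): the female pair alone falls from 2790 to 344 regions and the male pair alone rises from 23 to 202. Male regions beyond the 23 held a female peak in the full lists.

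The regions in both female and neither male library were more often weak than strong. When all regions in both female lists were put into 5 equal bins by p-value, 140 of these regions fell in the strongest bin. The weakest bin held 901 of them. The best-ranked region of the female pair alone lay on chromosome 9 from 24087624 to 24087921. It was at 6.88-fold (rank 272) in female 1 and 8.83-fold (rank 92) in female 2. Next came a region on the X chromosome from 91457817 to 91458595, at 6.11-fold and 6.42-fold in female 1 and 2. A further chromosome 9 region from 85750103 to 85750420 had 7.56-fold and 6.26-fold, and one on chromosome 10 from 38077706 to 38078151 had 6.43-fold and 6.16-fold. The remaining 6 of the 10 best-ranked were on chromosome 10 (29033272 to 29033538), 9 (118727607 to 118727955), 18 (9449830 to 9450146), 7 (51526729 to 51527073) and on X (92110925 to 92111346, and 146912403 to 146913355). So 3 of these 10 lay on X. No region of the female pair alone ranked within the first 250 peaks of both female lists, and 1 did within the first 500. Within the first 500, 58 regions were in all 4 lists, 5 were in the number 1 pair alone and 14 in the number 2 pair alone. The first 500 are a larger part of the shorter male lists, so these counts are not at equal thresholds.

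Of the 23 regions in both male and neither female library, the best-ranked lay on chromosome 11 from 18915971 to 18916443, at 4.22-fold (rank 1025) in male 1 and 5.09-fold (rank 1192) in male 2. The next ones were on chromosome 14 (34116618 to 34116924, at 3.81-fold and 4.70-fold), chromosome 11 (5442072 to 5442466, at 3.59-fold and 4.90-fold) and chromosome 11 again (3763540 to 3763844, at 3.38-fold and 4.47-fold). The other 6 of the 10 best-ranked were on chromosomes 13 (93381086 to 93381309), 1 (59483934 to 59484310), 16 (4214161 to 4214348), 7 (129245129 to 129245413), 3 (117278618 to 117278818) and 19 (5729454 to 5729735). At a stricter threshold, −log10 q of at least 5, the male pair alone held 15 regions and the female pair alone 1794. Of the 10 male regions named here, 1 was still in both male and neither female list at that threshold, and 5 were at equal list length by p-value.

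Male and female libraries of the same replicate number overlapped more than the libraries of the same sex. Of the peaks of male 1, 77.0% (95% exact interval 75.7 to 78.3) overlapped a peak of female 1, and 52.4% (50.9 to 53.9) overlapped a peak of male 2. Of the peaks of male 2, 80.7% (79.9 to 81.5) overlapped a peak of female 2. Of the peaks of female 1, 57.6% (56.9 to 58.4) overlapped a peak of female 2. The pairs that shared neither sex nor number overlapped by 68.2% (female 1 and male 2) and 64.7% (female 2 and male 1) of the shorter list. Circular shifts gave mean overlaps between 0.237% and 0.476%. These shares depend on list length. At 4155 peaks per list, male 1 overlapped female 1 by 43.7% (42.2 to 45.3) and male 2 by 33.3% (31.8 to 34.7), and male 2 overlapped female 2 by 54.1% (52.5 to 55.6). Female 1 and female 2 then overlapped by 45.5% (43.9 to 47.0), and female 1 and male 2, which share neither sex nor number, by 44.7% (43.2 to 46.2). The intervals of these 2 pairs overlap that of female 1 and male 1, so by p-value the overlaps of female 1 do not single out its own number. At equal length by fold enrichment, female 1 overlapped male 1 by 37.9%, female 2 by 28.6% and male 2 by 28.2%. Female 2 and male 1 overlapped by 32.6% (31.2 to 34.1) at equal length by p-value, and by 25.6% at equal length by fold enrichment. The 2 libraries of a number carry the same code in their descriptions, so number and code cannot be told apart. The Sex tag splits the libraries in the same way (number 1 tagged Female, number 2 tagged Male), so a higher overlap within a number is also a higher overlap within a tag. The intervals treat peaks as independent and cover counting error only.

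**Figure D3:**
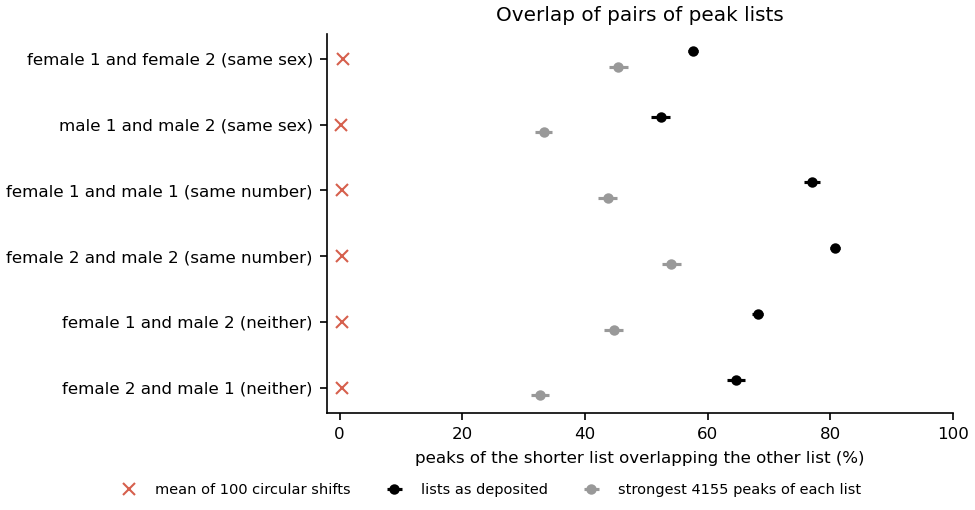
Share of the peaks of the shorter list that overlap the other list by at least 1 bp (x axis, %), for the 6 pairs of libraries, with 95% exact intervals as bars, for lists as deposited (black) and the strongest 4155 peaks of each list (grey). Crosses mark the mean of 100 circular shifts, at under 0.5% in each pair, while the observed overlaps lie between 32.6% and 80.7%.

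Whether a female region was also found in a male list went with its strength. The 9064 regions in both female lists were put into 5 equal bins by the lower of their ranks by p-value in the 2 lists. Of the strongest bin, 7.72% (6.53 to 9.05) were in no male list. The share was 20.7%, 32.7% and 43.1% in the next bins and 49.7% (47.4 to 52.1) in the weakest. Single lists binned by p-value showed the same order. In female 1, 80.5% of the strongest bin of peaks were in a male list, against 25.8% of the weakest. In female 2 the shares were 84.0% and 25.2%. The fall was not particular to the other sex. Of female 1 peaks, 87.6% of the strongest and 36.8% of the weakest bin were in female 2. Of female 2 peaks, 84.0% and 35.9% were in female 1. In the male lists, the strongest bin was in a female list for 94.7% (male 1) and 98.7% (male 2) of peaks, and the weakest for 74.2% and 76.2%.

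The sex chromosomes set the libraries apart by the sex in their titles. Peaks on X made up 1.65% (1.46 to 1.86) of female 1 and 1.78% (1.59 to 1.99) of female 2, against 0.890% (0.628 to 1.23) of male 1 and 0.929% (0.746 to 1.14) of male 2. On a log2 scale, the male share of X peaks relative to the female share was -0.89 in replicate number 1 and -0.94 in number 2. The 19 autosomes ranged from -0.12 to 0.23 and from -0.07 to 0.11. Fisher's exact test across peaks, of X against autosomes in male and female lists, gave an adjusted p of 0.000183 in number 1 and 3.44e-08 in number 2 (Benjamini-Hochberg over 2 tests). It compares these lists and not the sexes. At equal list length by p-value, the odds ratio was 0.741 in number 1 (adjusted p = 0.196, Fisher's exact test) and 0.469 in number 2 (adjusted p = 0.00387, Fisher's exact test). At equal length by fold enrichment, it was 0.296 in number 1 (adjusted p = 7.1e-12, Fisher's exact test) and 0.422 in number 2 (adjusted p = 3.5e-07, Fisher's exact test). The cut by fold raised the share of X itself, in female 1 from 1.65% to 2.96%, while male 1 was not cut. The cut by p-value lowered that share, in female 1 to 1.20%. The odds ratios of number 1 at equal length, by fold or by p-value, therefore do not tell whether list length explains the lower share. In number 2 both lists were cut. By fold, the share of X rose in both, to 2.70% in female 2 and 1.16% in male 2. By p-value it fell in both, to 1.28% and 0.602%. At −log10 q of at least 5, the odds ratio was 0.358 in number 1 (adjusted p = 0.00215, Fisher's exact test) and 0.470 in number 2 (adjusted p = 1.56e-05, Fisher's exact test). Of the 136 X regions in both female lists, 63.2% (54.5 to 71.3) were in no male list, against 30.3% (29.3 to 31.3) of the 8928 autosomal ones. No region on X was in both male lists and neither female list. That count says little about X, since there were 23 such regions in all and X held 460 of the 25223 merged regions. Chromosomes 2, 6, 8, 10, 17 and 18 had 0 as well.

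**Figure D4:**
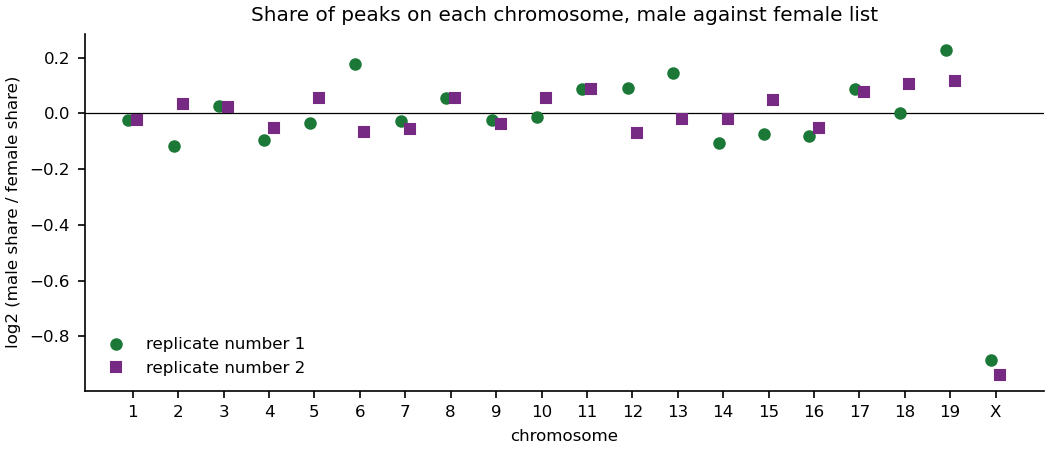
Log2 ratio of the share of peaks on each chromosome in the male list to that in the female list of the same replicate number (y axis), by chromosome (x axis), for number 1 (circles) and number 2 (squares). X lies at -0.89 and -0.94, below all 19 autosomes in both numbers.

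Peaks on Y sequence were present in both male lists and in neither female list. Male 2 had 23 peaks on Y, 21 of them between 2779664 and 2901844. Male 1 had none on Y and 16 on the unplaced Y contig of mm9, 12 of them between 17075877 and 17729164. The count of 0 in female 1 allows a share of up to 0.0186% of its peaks, and that in female 2 up to 0.0179%. The Y peaks of male 2 were weak, at a median of 1.88-fold against 3.80-fold for its whole list, and 0 of them were among its 4155 strongest peaks by fold. Those of male 1 had a median of 3.41-fold against 3.63-fold. Both number 1 lists had peaks on unplaced contigs, 22 in female 1 and 27 in male 1, and both number 2 lists had 0. A Sex tag in the labels goes against title and description for male 1, tagged Female, and female 2, tagged Male. By that tag, Y peaks would be in one library of each sex.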

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

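The female to male ratio of peak numbers (2.62) stayed above 1 at −log10 q of at least 5 and on chromosomes 1 to 19 and X, and ranged from 1.74 to 3.96 with each library left out. The replicate block, pairing libraries by number, gave the same ratio of 2.62 with an exact sign-flip p of 0.5, the smallest that 2 pairs can give, so it changed no call. With groups from the Sex tag, the ratio was 0.65 (exact permutation p = 0.667) and the regions of 1 tag alone were 508 (Female) and 1617 (Male). In the order female pair alone, male pair alone and all 4 libraries, region counts were 1794, 15 and 735 at −log10 q of at least 5, and 344, 202 and 774 at equal list length. They were 39, 13 and 100 for the top 500 peaks, 83, 38 and 167 for the top 1000, 167, 94 and 337 for the top 2000, and 241, 245 and 467 at equal length by fold. Fewer peaks enter each of these. The male pair alone rose above its 23 regions at equal length by either ranking and for the top 1000 and 2000. Cutting a list only removes peaks, so the regions beyond the 23 lay in regions that held a female peak in the full lists. With an overlap of at least 50% of both peaks, the male pair alone had 81 regions and all 4 libraries 1288. With summits within 200 bp, the male pair alone had 51. Leaving out a library gave 3313 (without male 1) to 8643 (without female 2) regions for females alone, 100 to 1199 (without male 1) for males alone and 2048 to 5748 (without male 1) for regions in all remaining libraries. Without male 2, females alone had 6554, and without female 1 they had 8627. A library left out loosens each rule, so these region counts rise by construction. Pairwise overlaps are given in the order female 1 and 2, female 1 and male 1, female 1 and male 2, female 2 and male 1, female 2 and male 2, male 1 and 2. They were 43.1%, 46.0%, 49.6%, 35.9%, 62.7% and 33.7% with 50% of both peaks. With summits within 200 bp they were 51.4%, 66.8%, 61.3%, 56.1%, 73.0% and 46.4%. At equal length they were 45.5%, 43.7%, 44.7%, 32.6%, 54.1% and 33.3%, and by fold 28.6%, 37.9%, 28.2%, 25.6%, 46.9% and 27.1%. X held 1.53%, 0.531% and 0.724% of peaks in female 2, male 1 and male 2 at −log10 q of at least 5, and 1.20%, 1.28% and 0.602% in female 1, female 2 and male 2 at equal length, or 2.96%, 2.70% and 1.16% by fold. Male 1 kept 3 Y peaks and male 2 kept 7 at −log10 q of at least 5, and male 2 kept 5 at equal length and 0 by fold. Equal list length gives no value for peak numbers. Promoter, motif and gene list results and their alternatives were not run, since they need mm9 sequence and annotation. Depth limits all counts, and the lists do not give it.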

Other observations

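Counts of regions by sex at equal list length and Y peaks per library were planned. The bins by strength, the overlaps and number pairs at equal length, the odds ratios for X and the window counts were tests chosen after the results were seen, as was the use of each value to weigh an explanation. Regions shared by all 4 libraries were unevenly spread. A stretch of 179 kb on chromosome 6, from 47544099 to 47723178 (mm9), held 28 of them, while the fullest 1 Mb window of 100 random placements, which kept the number per chromosome, held 8. Their median fold enrichments were 2.89 and 2.51 in female 1 and 2, and 2.56 and 2.68 in male 1 and 2, below the list medians of 3.63, 3.78, 3.63 and 3.80. The next windows were on chromosome 10 from 79000001 to 80000000, with 15 shared regions, and on chromosome 13 from 23000001 to 24000000, with 11. Merged regions of any kind numbered 54 in the chromosome 6 window, 106 in that of chromosome 10 and 47 in that of chromosome 13. The random placements ignored how all peaks cluster, so part of these counts may follow general peak density. Regions of the female pair alone did not cluster in this way: their fullest windows held 9 regions, and random placements reached 10.

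A few strong regions were tied to a replicate number or to 1 library, and others were missing from male 1 alone, the shortest list. The region on chromosome 17 from 56339321 to 56339616 was the 8th strongest of male 1 by fold (10.6-fold), was at 6.38-fold in female 1, and was in neither number 2 list. The region on chromosome 1 from 7384678 to 7385234 ranked 36 in female 2 (10.7-fold), was at 6.81-fold in male 2, and was in neither number 1 list. The region on chromosome 11 from 98885399 to 98885951 was missing from male 1 alone. It had 11.3-fold in female 2 and 12.1-fold in male 2, against 2.69-fold in female 1, so it was not confined to a number. Also missing from male 1 alone were regions on chromosome 11 from 23155092 to 23156526 (15.8-fold in female 1) and on chromosome 9 from 20635366 to 20635777 (9.62-fold in male 2). The region on chromosome 6 from 132413643 to 132413909 ranked 12 in male 1 (9.42-fold) and was in no other list. These regions were chosen after their values were seen.

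Both female and neither male list held 2790 regions, against 23 the other way. With 1 library left out the rule is looser, so the counts rise by construction. They ranged from 3313 (without male 1) to 8643 (without female 2) and from 100 (without female 2) to 1199 (without male 1). Weak peaks missed in the shorter male lists are a candidate explanation: of the regions in both female lists, 7.72% of the strongest of 5 equal bins were in no male list, against 49.7% of the weakest. This gradient does not single out the male lists. The share of female 1 peaks found in female 2 also fell, from 87.6% in the strongest bin to 36.8% in the weakest. A lower depth and a weaker YAP1 signal in the male tumours would both leave weak peaks out of the male lists, and the lists hold nothing to separate them. A sex difference in which sites YAP1 occupies stays open. At equal list length, 546 regions were confined to a sex pair, against 439 for the crossed pairs and 1264 for the pairs of a number. Such regions include ones whose peak in another list was cut, so the 546 do not count sex-specific binding. With lists as deposited, the totals were 2813, 543 and 2125. With 2 libraries per sex and 3 ways to pair them, chance cannot be judged.

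The male lists overlapped the female list of their own number more than each other, and the number of peaks alone does not account for it. At equal length the lower of the same-number overlaps was 43.7%, with an interval above that of the male lists (33.3%). Male 1 was not cut and kept its weaker peaks, so a difference in depth or quality behind list length stays in this comparison. Male 2 also overlapped female 1, which shares neither sex nor number with it, by 44.7%. The contrast with the male pair therefore does not single out the number. A batch marked by the shared code in the descriptions may account for the higher overlap within a number. At equal length, 1264 regions were in the cut lists of a number alone, against 546 for the sexes and 439 for the crossed pairs. Each count can include regions whose peak in another list was cut. With lists as deposited the sexes came first, with 2813 against 2125 for the numbers, so this order depends on list length. The overlaps of female 1 at equal length depend on the ranking: by p-value they were 43.7% with male 1, 44.7% with male 2 and 45.5% with female 2, with intervals that overlap, and by fold 37.9%, 28.2% and 28.6%. Peaks on unplaced contigs were in both number 1 lists and in neither number 2 list, so the numbers may also differ in the contigs they were aligned to. Whether the code stands for animals, chromatin preparation, sequencing, alignment or a shared control stays open, and the Sex tag follows the same split.

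Male lists had a smaller share of peaks on X. In number 2, different lengths of the lists do not account for all of it. There the odds ratio at equal length by p-value was 0.469 (adjusted p = 0.00387, Fisher's exact test). Number 1 gave 0.741 (adjusted p = 0.196, Fisher's exact test). It cannot decide, since male 1 was not cut and the cut lowered the X share of female 1. The pooled odds ratio of 0.601 (95% interval 0.438 to 0.825) includes number 1 and so rests on number 2. A batch shared by both libraries of a number does not account for the smaller share with lists as deposited, where the odds ratio was 0.537 in number 1 and 0.518 in number 2. Handling or depth that differed between the male and the female library of a number cannot be told apart from sex in this comparison. A hypothesis is that the share follows the single X of male animals: both male lists had Y peaks, at least 16 each, and both female lists had 0. Titles that are wrong with a Sex tag that is right is argued against by 16 Y peaks in the library titled male 1 and tagged Female. The library titled female 2 and tagged Male had 0 Y peaks. Since the number 2 lists have no peaks on any unplaced contig, that 0 concerns Y itself, where male 2 had 23 weak peaks. Male 1 also had 0 peaks on Y itself, so a 0 there does not show that female 2 lacks a Y. Whether YAP1 also binds X differently in the sexes, beyond the number of X copies, was not tested.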
